A study of Mus musculus with 8 samples.

How the data were processed

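RNA-seq was made from 8 pools of 12 to 18 mouse embryos at the 2-cell stage, 4 Dux KO and 4 WT, and groups and replicate numbers were taken from the sample labels. The authors deposited a table of genes and a table of repeat names. Gene values are FPKM, and each library's values are whole multiples of 1 step after a factor per gene is taken out. The steps did not follow the totals of gene reads recovered as described below. The step was 1.12 in WT replicate 3 at 13248986 reads and 0.932 in Dux KO replicate 1 at 13010944 reads. The values were therefore taken to be scaled between libraries by size factors, which is an inference. Repeat values are FPM (fragments scaled to library size), as the deposited repeat table's own name for them says. Both deposited tables also hold a mean signal, read here as the mean over samples of counts divided by size factors, a log2 fold change and a Benjamini-Hochberg adjusted p-value of the authors. Trimmomatic 0.32, STAR 2.6.1a, SAMtools 1.7 and the genome build GRCm38 (mm10) are named per the submitters' processing notes. The read counter, the annotation, the strand setting, the treatment of reads with several positions and the authors' test are not given in the sources used here. Reads that fit several copies of a gene or repeat can therefore have been dropped, split or counted more than once.

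The gene table holds 13101 genes, none with a mean count under 25.0, so that low genes had been left out before. Of these, 66 carry no symbol, and 13100 identifiers were found in GENCODE M21, from which coordinates were taken; 1 was not found. The repeat table holds 1554 names, 69 of them at 0 in every sample and 415 without a deposited adjusted p-value. The deposited fold change had the sign of the ratio of mean FPKM for 99.9% of genes. The number of numeric columns left unmapped to a sample was 0. The knocked-out gene was not analysed here, since 0 rows matched it.

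Whole reads were recovered from the steps of both tables, with 100% of values whole within 0.05. They gave 12343369 to 14548526 gene reads and 2239838 to 3008546 repeat reads per library. The 10 most abundant genes took 14.5 to 18.7% of gene reads. Column totals of FPM were 1019090 to 1183120 in WT and 834571 to 951000 in Dux KO, so that FPM values were not scaled to 1 total. Pairs of libraries of a group were compared by a chi-square of recovered reads over genes.

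Expression was tested with limma 3.58.1 in R 4.3.3, with a variance trend and robust variance moderation, on log2(FPKM + 1) for genes with a mean of at least 0.5 FPKM and on log2(FPM + 1) for repeats with a mean of at least 1 FPM, leaving 12434 genes and 1267 repeats. All 8 samples entered with no covariate. Genes and repeats with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. All p-values are two-sided. MERVL-int and MT2_Mm were also tested by exact permutation over the 35 splits of the samples.

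The 18 gene lists and 8 repeat lists were written from textbook knowledge before the data were examined. They cover 2-cell-stage DUX-responsive genes, early zygotic genes outside that list, oocyte and maternal-effect transcripts, regulators of genome activation, pluripotency and inner cell mass genes, trophectoderm genes, p53 targets, apoptosis, heat shock and unfolded protein response, interferon and innate immunity, cell cycle, nuclear oxidative phosphorylation, ribosomal proteins and mitochondrially encoded genes. Markers of cumulus and granulosa cells, oviduct epithelium, blood and sperm stand for other cells that a pool could carry. Both Eif1a and Eif1ax counted in the early zygotic list, where they had been meant as names of the same gene. The repeat lists cover MERVL, related ERVL LTRs, MaLR, IAP, other ERVK, L1, B1 and B2 SINEs, and satellites. Lists with at least 5 tested genes or 3 tested repeats, 16 and 7 in number, were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation and with fry.

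The rule for named genes was also set before. It took the 12 genes of largest change in each direction among those called, with a mean of at least 1 FPKM in the higher group and no overlap of the 4 and 4 values, leaving out predicted gene models. From each list it took at most 4 members called in each direction, or the 2 most abundant where none was called. Of repeats it took MERVL-int, MT2_Mm and the 5 of largest change in each direction.

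Alternatives set before were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM or 10 FPM, quantile normalization (genes), median-of-ratios scaling, the replicate number as a block, limma without trend and robust moderation, the deposited p-values, an estimated correlation, fry, and leaving out each sample. Alternatives chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out Dux KO replicates 1 and 2 or 3 and 4 together. On recovered reads, edgeR called 4336 genes and DESeq2 4918, of which 3887 and 4034 were called by limma in the same direction.

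The tests were tried on simulated data for this comparison. Of genes changed 1.5-fold, 2-fold and 4-fold among 12434, limma recovered 1.49%, 29.9% and 90.9%, and edgeR 2.99%, 50.7% and 95.5%. Of repeats among 1267, limma recovered 38.8%, 68.7% and 87.9%. Of the genes and repeats that limma called there, 2.38% and 8.1% were unchanged ones. The simulation left 12194 of the genes and 1027 of the repeats unchanged, so that its recovery is not that of the real comparison. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.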

Results

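RNA was measured in 8 pools of mouse 2-cell embryos, 4 from a line with a knockout of Dux (Dux KO) and 4 wild type (WT). Dux encodes a double homeobox transcription factor of the early embryo, known to activate a set of 2-cell-stage genes and MERVL, an endogenous retrovirus whose long terminal repeat (LTR) is MT2_Mm. Each pool held 12 to 18 embryos of the C57BL/6 background. The gene table held 13101 genes and 12343369 to 14548526 recovered reads per pool, and the repeat table held 1554 repeat names and 2239838 to 3008546 reads per pool. Pools of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 13.8 to 117, so that no pair looked like 1 library deposited again. This does not show that the pools are independent. The labels do not say whether the 4 pools of a group came from separate parents, and p-values measure the spread between these pools.

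The comparison asks which transcripts of 2-cell embryos change when Dux is lost. The Dux transcript itself, which would check the labels of the pools, was not analysed here, since no row of the gene table used carries its symbol or identifier.

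MERVL-int, the internal part of MERVL, was lower in all 4 Dux KO pools than in any WT pool. Its level was 13764 ± 2082 FPM in WT and 5445 ± 655.3 FPM in Dux KO (SD, n = 4), a log2 fold change of -1.33 (95% interval -1.61 to -1.06, limma adjusted p = 3.27e-05; exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 pools can give). In the authors' deposited table the log2 fold change of MERVL-int was -1.34. MT2_Mm, its LTR, fell from 10114 ± 2355 to 5957 ± 612 FPM (log2 fold change -0.74, limma adjusted p = 0.00716; exact permutation p = 0.0286, two-sided). Both tested members of the MERVL list thus fell, also adjusted over the list alone.

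**Figure D1:**
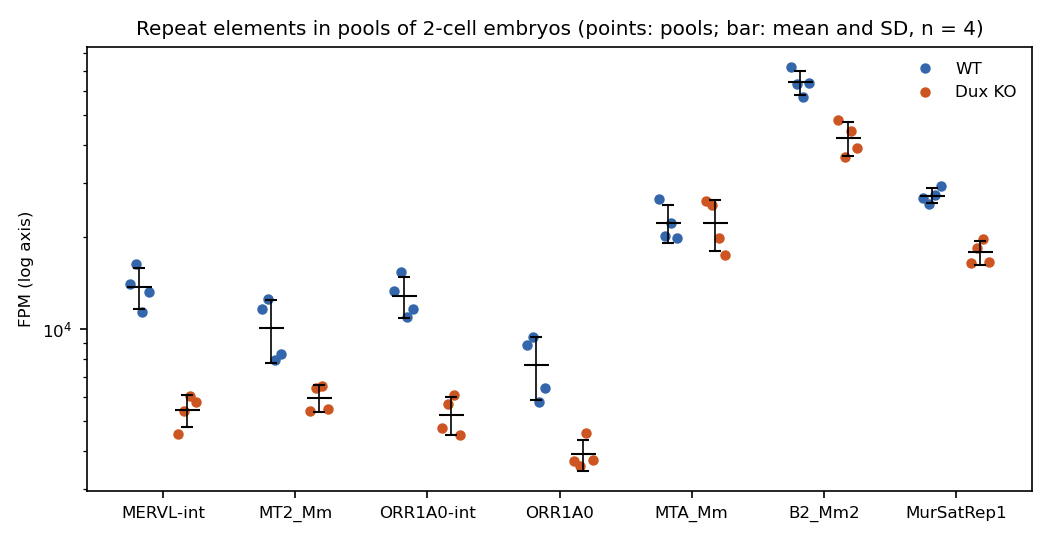
FPM on a log axis for 7 repeat elements in each pool of 2-cell embryos, with WT in blue and Dux KO in orange; black bars give the mean and SD of 4 pools. MERVL-int lies at 4548 to 6050 FPM in Dux KO pools and at 11360 to 16381 FPM in WT pools, whereas MTA_Mm overlaps between the groups (22256 ± 3150 FPM in WT, 22238 ± 4194 in Dux KO).

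Of 1267 repeat names tested, 59 were higher and 96 lower in Dux KO (limma, adjusted p under 0.05). Repeats named in the next paragraphs beyond the 5 of largest change in each direction were chosen after their values were seen. Among ERVL elements related to MERVL, 4 of 6 fell and none rose; adjusted over the list alone, 4 fell and 1 rose, as also by DESeq2 on recovered reads. MT2B fell from 6000 ± 422 to 3466 ± 364 FPM (log2 fold change -0.79), and MERVL_2A-int from 2164 ± 347 to 1140 ± 113 FPM (log2 fold change -0.92). MT2B1 did not pass (12608 ± 1017 and 11300.0 ± 496 FPM, limma adjusted p = 0.326). The list's camera adjusted p was 0.000998, and its adjusted p was 0.245 with an estimated correlation.

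MaLR elements, a further group of LTR retrotransposons active in oocytes and early embryos, split into parts that fell and parts that did not pass. Of 48 tested, 13 fell and none rose by limma, while on recovered reads edgeR gave 15 lower and 3 higher and DESeq2 17 and 4 (15 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.000998, adjusted p = 0.645 with an estimated correlation). The 13 that fell were mostly of the ORR1A and ORR1B types. ORR1A0-int fell from 12821 ± 1979 to 5260 ± 758 FPM and ORR1A1-int from 13912 ± 2119 to 5236 ± 887 FPM (log2 fold changes -1.28 and -1.41). Both stood close to MERVL-int in level, and reads of MERVL-int may have been counted for them too. The LTR ORR1A0 fell by 0.94 on the log2 scale, from 7623 ± 1776 to 3901 ± 458 FPM. MTA_Mm-int did not pass (67555 ± 11487 and 58764 ± 11941 FPM, limma adjusted p = 0.396).

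B1 and B2 SINEs, short elements spread through many genes, fell in 13 of 21 names and rose in none (19 fell adjusted over the list alone; camera adjusted p = 2.70e-09, adjusted p = 0.268 with an estimated correlation). B2_Mm2 fell from 64130 ± 5886 to 42136 ± 5313 FPM and B1_Mus2 from 10719 ± 367 to 7994 ± 977 FPM (log2 fold changes -0.61 and -0.43). Of 5 satellite repeats 2 fell, MurSatRep1 (log2 fold change -0.62) and MMSAT4 (-0.43), with the same number adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.245 with an estimated correlation). L1 elements rose in 6 and fell in 4 of 125 names by limma (11 and 4 by edgeR and 18 and 6 by DESeq2 on recovered reads), and L1Md_A fell from 505 ± 27.0 to 352 ± 43.4 FPM. Adjusted over the list alone, 5 rose and 2 fell; the median was 0.05, the camera adjusted p 0.0189, and the adjusted p 0.645 with an estimated correlation. Without Dux KO replicate 1, and without replicates 1 and 2, the call of the L1 list ended (camera adjusted p = 0.312 and 0.535, medians 0.02 and -0.02). The median was 0.09, 0.10, 0.03 and 0.03 without WT replicates 1, 2, 3 and 4 in turn. It was 0.08, 0.11 and 0.09 without Dux KO replicates 2, 3 and 4 in turn, and 0.15 without Dux KO replicates 3 and 4 together.

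IAP elements did not pass as a list (camera adjusted p = 0.2001) but did without WT replicate 4 (median -0.19, camera adjusted p = 0.0479), and by limma 1 of 25 fell, IAPEY4_LTR, from 33.0 ± 9.61 to 14.3 ± 6.27 FPM, also adjusted over the list alone. On recovered reads 5 fell by edgeR and by DESeq2, and 1 rose by DESeq2. Other ERVK elements did not pass either (camera adjusted p = 0.0848), with 7 higher and 22 lower of 202, over all repeats and adjusted over the list alone. Without WT replicate 3 that list passed (median -0.16, camera adjusted p = 0.0203). RLTR47, of that list, fell from 246 ± 81.7 to 77.5 ± 21.6 FPM (log2 fold change -1.63). Of single repeats, LTR102_Mam fell most (85.9 ± 32.0 to 21.7 ± 11.2 FPM, log2 fold change -1.96), followed by HY1 (-1.77), RLTR47, MLT2E (-1.59) and MLT1C-int (-1.58). HY1 was low in both groups (5.28 ± 1.76 FPM in WT, 0.898 ± 0.691 in Dux KO). MER70A rose most, from 21.5 ± 7.52 to 70.6 ± 27.3 FPM (log2 fold change 1.66), and Eulor4, MER97a, L1MEg2 and LTR89 rose by 1.34 to 1.47 from levels under 5 FPM. These folds are on the log2(FPM + 1) scale, which understates changes of low repeats. Eulor4, MER97a, L1MEg2 and LTR89 lost their calls in 9, 5, 2 and 7 of 16 alternatives, and LTR89 overlapped between the groups. The count of 155 changed repeats was 90 without WT replicate 4, 103 without Dux KO replicate 1, 63 without Dux KO replicate 2 and 31 without both Dux KO replicates 1 and 2, against 106 without both replicates 3 and 4.

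Of 12434 genes tested, 1933 were higher and 2249 lower in Dux KO, and 468 and 408 of them changed at least 2-fold (limma on log2(FPKM + 1), adjusted p under 0.05). The 2 groups of pools did not overlap for 4118 genes, 33.1% of those tested, where chance gives 2.86%. The first principal component held 58.1% of the variance and set the groups apart. By the authors' deposited table, higher genes numbered 2120 and lower genes 2433. With median-of-ratios scaling they numbered 2076 and 2046, and with a mean of at least 5 FPKM required 1032 and 1880. The total of 4182 changed genes was 2522 without WT replicate 4, 2682 without Dux KO replicate 1 and 795 without both Dux KO replicates 1 and 2, against 3944 without both replicates 3 and 4. The total of 876 genes changed at least 2-fold was 1697 by edgeR on recovered reads (1088 higher and 609 lower), 1786 by DESeq2 (1153 and 633), 360 without Dux KO replicates 1 and 2, 1560 without replicates 3 and 4, and 1596 with a pseudocount of 0.1 (920 and 676). More of them were lower than higher without WT replicate 3 (436 higher, 461 lower) and without Dux KO replicate 3 (500 and 590). With all 8 libraries this was also so at a mean of at least 5 FPKM (324 and 339).

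The 12 named genes that rose most in Dux KO, by 1.88 to 2.37 on the log2 scale, were Stra8, Ripk3, AA545190, Tac2, Pkd2l2, Lmo1, Reep1, Lyn, Stard3nl, Pla2g1b, Pard3bos2 and Sult1c1. Stra8, known for its part in the start of meiosis, was at 0.852 ± 0.521 FPKM in WT and 8.58 ± 2.56 FPKM in Dux KO (log2 fold change 2.37, limma adjusted p = 0.000802). It lies on chromosome 6 at 34920163 to 34939344 (GRCm38). Ripk3, a kinase of necroptosis, rose from 1.23 ± 0.776 to 9.60 ± 2.49 FPKM. WT replicate 3 alone held 2.39 FPKM of Ripk3, with the other WT pools at 0.781 to 0.895. Lmo1, a LIM domain transcriptional cofactor, and Pkd2l2, of the polycystin channel family, were abundant and rose from 122 ± 34.0 to 527 ± 220.2 FPKM and from 111 ± 33.7 to 472 ± 147 FPKM. AA545190, a long noncoding RNA, rose from 182 ± 79.7 to 843 ± 401 FPKM. Tac2, which encodes the precursor of neurokinin B, rose from 6.63 ± 2.81 to 34.9 ± 24.5 FPKM. The rule left out 277 predicted gene models among the 1507 genes that qualified as higher, 9 of them with a larger change than the last of the 12.

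The 12 named genes that fell most, with log2 fold changes down to -2.71, were mt-Tr, Nfe2, Rbm8a2, Olfr881, AC153137.1, Fbxo6, Zfp981, Prdm14, Kyat3, Wdr55, Ercc1 and Nanos3. Nfe2, a transcription factor best known from blood cells, fell from 11.8 ± 3.66 to 1.66 ± 1.12 FPKM (log2 fold change -2.33, limma adjusted p = 0.00202). Prdm14, a regulator of pluripotency and of the germ line (chromosome 1 at 13113457 to 13127163, GRCm38), fell from 14.1 ± 5.37 to 3.19 ± 1.97 FPKM (log2 fold change -1.91). Nanos3, an RNA-binding protein of germ cells, fell from 19.6 ± 7.26 to 5.19 ± 1.90 FPKM. Fbxo6, a subunit of a ubiquitin ligase that binds glycoproteins, fell from 34.0 ± 5.12 to 7.95 ± 3.31 FPKM, and Wdr55 from 77.6 ± 13.3 to 23.0 ± 8.93 FPKM. Ercc1, a partner in a nuclease of nucleotide excision repair, fell from 42.9 ± 11.1 to 12.4 ± 4.53 FPKM. The rule left out 243 predicted models among the 1899 genes that qualified as lower, 10 of them with a larger change than the last of the 12.

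The transfer RNA gene mt-Tr of the mitochondrial genome (9808 to 9875) was not lower to a like degree in all Dux KO pools. It stood at 40.5 and 46.8 FPKM in Dux KO replicates 1 and 2, 2.98 and 6.33 FPKM in replicates 3 and 4, and 75.2 to 122 FPKM in WT. Its neighbour mt-Nd3, a subunit of respiratory complex I (9459 to 9806), was at 411 to 753 FPKM in WT and at 213, 281, 0.194 and 0.412 FPKM in Dux KO replicates 1 to 4. Gm28438, a nuclear copy of mt-Nd3 on chromosome 1 (24612775 to 24613119, GRCm38), was chosen after its values were seen. It was at 0.236 to 1.54 FPKM in WT and at 199.9, 1.11, 632 and 872 FPKM in Dux KO replicates 1 to 4. Recovered reads lay almost wholly on 1 of the 2 in each pool but Dux KO replicate 1, with 1078 on mt-Nd3 and 1001 on Gm28438. WT pools held 1985 to 3158 reads of mt-Nd3 and 1 to 7 of Gm28438, and Dux KO replicate 2 held 1537 and 6. Dux KO replicates 3 and 4 held 1 and 2 reads of mt-Nd3 and 3232 and 4191 of Gm28438. Values of these copies stay uncertain, since reads of 1 can be assigned to the other.

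**Figure D2:**
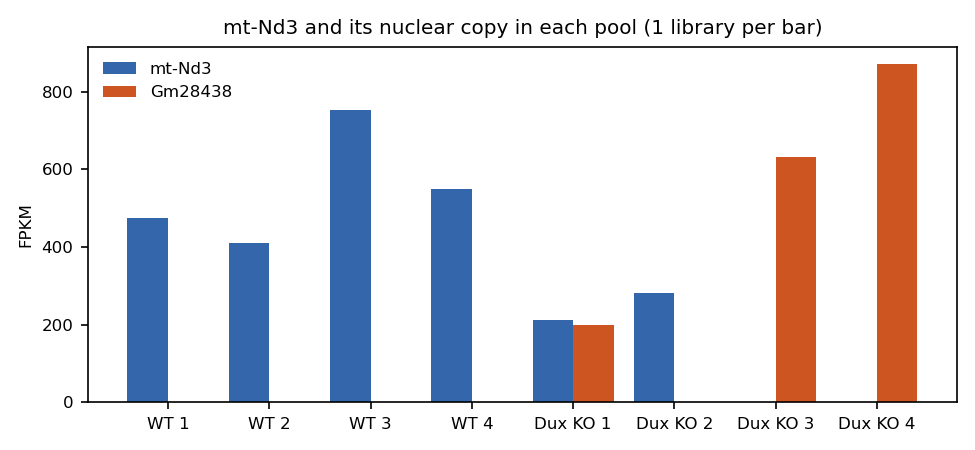
FPKM of mt-Nd3 (blue) and of its nuclear copy Gm28438 (orange) in each pool, 1 library per bar. In Dux KO replicates 3 and 4 mt-Nd3 is at 0.194 and 0.412 FPKM and Gm28438 at 632 and 872 FPKM, while WT pools hold mt-Nd3 at 411 to 753 FPKM.

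Among 2-cell-stage genes known to respond to DUX, 10 of 34 tested fell in Dux KO, none rose and 24 did not pass, with the same counts adjusted over the list alone. Gm21319 fell from 5.93 ± 2.55 to 1.66 ± 1.05 FPKM, Gm5039 from 18.1 ± 6.15 to 7.67 ± 5.07, Gm8300 from 21.96 ± 6.98 to 10.5 ± 6.59 and B020004J07Rik from 46.2 ± 13.5 to 21.8 ± 4.52 (log2 fold changes -1.38, -1.28, -1.15 and -1.03). Gm8300 and Gm5039 overlapped between the groups and lost their calls in 9 and 7 of 19 alternatives. The others that fell were Ubtfl1, Zscan4f, Zscan4a, Slc34a2, Tdpoz1 and AF067063. Zfp352, a zinc finger gene of the 2-cell stage, did not pass, at 58.2 ± 17.1 FPKM in WT and 56.3 ± 13.8 in Dux KO (log2 fold change -0.02). Usp17lb was at 108 ± 31.6 and 102 ± 18.9 FPKM, and Tcstv3 at 56.2 ± 22.8 and 53.5 ± 23.0 FPKM, neither passing; these 3 genes were picked after their values were seen. The list's median was -0.26 (-0.15 without WT replicate 3) and it did not pass against the other genes (camera adjusted p = 0.145; adjusted p = 0.597 with an estimated correlation). Many members are near-identical copies in clusters, so that their reads may have been split. The list did pass without WT replicate 4, without Dux KO replicate 2 and without Dux KO replicates 1 and 2 (camera adjusted p = 0.0236, 0.0181 and 0.0367). At an unadjusted p under 0.05 limma gave 12 members lower and 0 higher. At an adjusted p under 0.05 edgeR on recovered reads gave 9 and 0.

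Early zygotic genes outside that list, most of which serve ribosome assembly, splicing, protein folding or degradation, fell in 18 of 40 and rose in none (21 and none adjusted over the list alone). Psmb5, a catalytic proteasome subunit, fell from 87.7 ± 15.9 to 38.9 ± 11.7 FPKM (log2 fold change -1.20). Pdxk fell by 0.96, Sf3b4, a splicing factor, by 0.92 and Nop2, a nucleolar RNA methyltransferase, by 0.88 on the log2 scale. The list passed (median -0.51, camera adjusted p = 3.60e-06), and its adjusted p was 0.597 with an estimated correlation. Ribosomal protein genes fell in 43 of 80 and rose in none (51 and none adjusted over the list alone; median -0.56, camera adjusted p = 4.65e-11, adjusted p = 0.597 with an estimated correlation). Rps23 fell from 36.6 ± 2.97 to 14.1 ± 2.94 FPKM (log2 fold change -1.33, limma adjusted p = 0.00202), Rps6 from 10.8 ± 3.07 to 4.74 ± 1.68 and Rpl19 from 17.1 ± 3.46 to 8.12 ± 2.68. Rpl3l, a paralogue best known from striated muscle, fell by 1.33 on the log2 scale. By edgeR on recovered reads (adjusted p under 0.05) 38 ribosomal protein genes were lower and 0 higher, and at an unadjusted p limma gave 58 and 1.

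**Figure D3:**
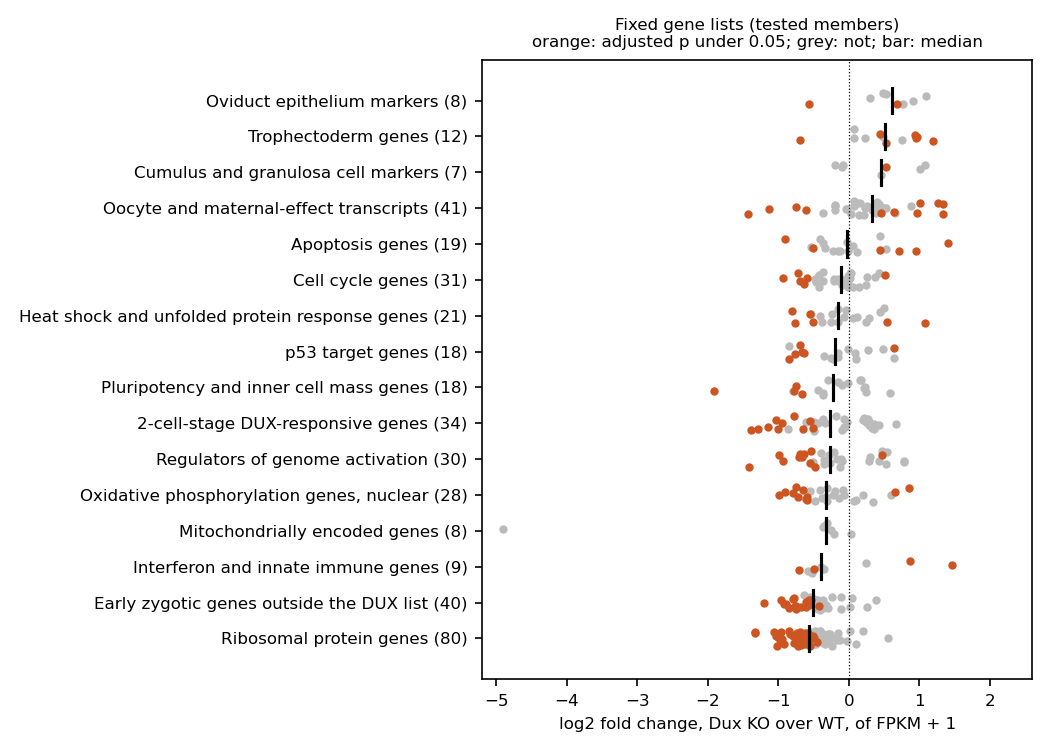
Log2 fold change of FPKM + 1, Dux KO over WT, of each tested member of the 16 gene lists with at least 5 tested members; orange points have an adjusted p under 0.05, grey points do not, and black bars are list medians. No ribosomal protein or early zygotic gene is among those that rose, and the medians of these lists are -0.56 and -0.51.

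Oocyte and maternal-effect transcripts moved both ways: 7 of 41 rose, 4 fell and 30 did not pass, with the same counts adjusted over the list alone. On recovered reads, edgeR gave 9 higher and 4 lower, and DESeq2 15 and 4. Btg4, which helps to clear maternal mRNA, rose from 428 ± 117 to 1200 ± 708 FPKM, though the groups overlapped. It stood at 494 FPKM in Dux KO replicate 4, at 2183 FPKM in Dux KO replicate 2 and at 300 to 545 FPKM in WT. Bmp15, an oocyte growth factor, rose from 110.2 ± 27.7 to 283 ± 98.2 FPKM, and Bcl2l10 and Cnot6l rose by 1.27 and 1.01 on the log2 scale. Bcl2l10 also overlapped between the groups, with 222 FPKM in Dux KO replicate 4 and 117 to 229 FPKM in WT. Zar1l, Zp3, Padi6 and Dppa3 fell, with log2 fold changes of -1.42, -1.13, -0.75 and -0.61. Zp3, a zona pellucida glycoprotein, fell from 198 ± 20.03 to 91.5 ± 19.9 FPKM, and Dppa3, a maternal protector of DNA methylation, from 5244 ± 467 to 3445 ± 279 FPKM. The list had a median of 0.33 and did not pass (camera adjusted p = 0.0508, adjusted p = 0.597 with an estimated correlation). It passed in 7 of 18 alternatives, among them those without WT replicate 2 and without Dux KO replicate 4 (camera adjusted p = 0.0388 and 0.00338). Without Dux KO replicates 1 and 2 its median was 0.13 (camera adjusted p = 0.367).

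Regulators of genome activation fell in 10 of 30 and rose in 1 by limma (11 and 2 adjusted over the list alone). On recovered reads, edgeR gave 9 lower and 5 higher, and DESeq2 10 and 8. Obox3, an oocyte-specific homeobox gene, fell from 50.0 ± 18.7 to 17.9 ± 5.49 FPKM and Obox6 from 1351 ± 167 to 729 ± 202 FPKM (log2 fold changes -1.41 and -0.93); Obox genes have near-identical copies, so that these values are uncertain. Dppa2, which acts upstream of Dux in embryonic stem cells, fell from 93.3 ± 20.1 to 48.1 ± 15.6 FPKM, and Hdac1, a histone deacetylase, by 0.70 on the log2 scale. Chaf1b, of a chromatin assembly factor, rose from 11.9 ± 0.730 to 17.1 ± 2.63 FPKM and lost its call in 7 of 19 alternatives. The list did not pass (camera adjusted p = 0.202). Pluripotency and inner cell mass genes fell in 4 of 18 and rose in none by limma (3 and none adjusted over the list alone; 5 lower and 1 higher by DESeq2 on recovered reads), namely Prdm14, Fbxo15 (591 ± 129 to 350 ± 102 FPKM), Fgf4 and Dppa5a, and did not pass as a list (camera adjusted p = 0.298). Fbxo15 and Fgf4 overlapped between the groups and lost their calls in 5 and 9 of 19 alternatives.

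Trophectoderm genes rose in 6 of 12 and fell in 1, also adjusted over the list alone, and passed as a list (median 0.51, camera adjusted p = 0.0204; adjusted p = 0.583 with an estimated correlation). Id2, an inhibitor of helix-loop-helix factors, rose from 26.0 ± 11.4 to 58.9 ± 18.0 FPKM. Gata2 rose from 0.262 ± 0.0508 to 1.46 ± 0.380 FPKM, and Dab2 and the glucose transporter gene Slc2a1 by 0.97 and 0.94 on the log2 scale. Tead4, a transcription factor needed for the trophectoderm, fell from 8.05 ± 2.36 to 4.60 ± 1.49 FPKM. It overlapped between the groups and lost its call in 7 of 19 alternatives. With a mean of at least 5 FPKM required, 6 members stayed and the list did not pass (camera adjusted p = 0.152). Cumulus and granulosa cell markers and oviduct epithelium markers stood beside these changes with medians of 0.46 and 0.61, neither list passing (camera adjusted p = 0.330 and 0.224). These medians were 0.12 and 0.40 without Dux KO replicate 2, 0.19 and 0.41 without WT replicate 3, and 0.13 and -0.04 without Dux KO replicates 1 and 2. Cyp19a1, an aromatase of granulosa cells, rose from 0.420 ± 0.147 to 1.06 ± 0.311 FPKM, as 1 of 7 tested markers. Of 8 oviduct markers Cdh1 rose and Epcam fell, both also known from embryos. These counts were the same adjusted over the list alone. Without Dux KO replicates 3 and 4 the oviduct list passed (median 1.14, camera adjusted p = 0.0291).

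Nuclear genes of oxidative phosphorylation fell in 9 of 28 and rose in 2 (10 and 2 adjusted over the list alone). Ndufa2 fell from 713 ± 14.8 to 381 ± 45.6 FPKM, while Ndufa4 rose from 128 ± 30.6 to 231 ± 60.6 FPKM and Ndufa1 from 165 ± 41.0 to 257 ± 41.5 FPKM. The list did not pass (camera adjusted p = 0.0508) and passed in 10 of 18 alternatives, among them those without WT replicate 2 or 3 or Dux KO replicate 3 or 4 (camera adjusted p = 0.0468, 0.0304, 0.0374 and 0.0297). None of 8 mitochondrially encoded genes passed in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.224); at an unadjusted p under 0.05 limma gave 1, mt-Nd3, and at an adjusted p edgeR and DESeq2 on recovered reads gave 0. Without Dux KO replicates 3 and 4 the list passed (median -0.50, camera adjusted p = 0.0364). mt-Cytb was at 52202 ± 2402 FPKM in WT and 41284 ± 5589 in Dux KO, and mt-Nd1 at 37922 ± 8140 and 29568 ± 7966.

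Stress and cell cycle lists did not pass as lists, and single members changed in both directions. Of 31 cell cycle genes 1 rose, Ccnd1 at under 1 FPKM, and 5 fell, with Gmnn, an inhibitor of replication licensing, from 1298 ± 119 to 683 ± 99.0 FPKM and Ccnb1 from 134 ± 22.2 to 82.7 ± 12.8 FPKM (camera adjusted p = 0.224). Of 18 p53 target genes 5 fell, among them Gadd45a (12.2 ± 1.501 to 6.55 ± 2.04 FPKM) and Sesn2, and Plk2 rose (camera adjusted p = 0.330). Plk2 lost its call in 8 of 18 alternatives. Of 19 apoptosis genes 4 rose and 2 fell, with Bik, a BH3-only protein, from 4.14 ± 1.32 to 13.0 ± 5.24 FPKM and Casp6 from 11.01 ± 2.50 to 5.45 ± 1.63 FPKM. That list had a median of -0.03, a mean of 0.06 and an upward test (camera adjusted p = 0.816). Of 21 heat shock and unfolded protein response genes 2 rose and 4 fell, with Hspe1 from 10.5 ± 1.76 to 23.7 ± 6.07 FPKM and Dnajb1 from 47.3 ± 10.2 to 26.6 ± 5.40 FPKM (camera adjusted p = 0.612). Counts in these 4 lists were the same adjusted over the list alone. Of 9 interferon and innate immune genes Cxcl10 and Ddx58 rose and Stat2 and Bst2 fell, 2 and 3 adjusted over the list alone (camera adjusted p = 0.572). Cxcl10, a chemokine, rose from 5.41 ± 1.98 to 16.6 ± 4.52 FPKM.

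Markers of blood and sperm were too few for a list test, with 2 tested members each. Cd52 and Cd79a, of blood cells, did not pass (3.26 ± 1.40 and 3.39 ± 1.88 FPKM, and 1.84 ± 0.653 and 2.16 ± 0.468 FPKM). Odf2 rose from 4.14 ± 0.437 to 7.63 ± 2.53 FPKM and Ldhc fell from 67.3 ± 15.0 to 36.5 ± 9.57 FPKM, both also adjusted over the list alone. All gene fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. With an estimated correlation between genes, none of the 3 gene lists and none of the 5 repeat lists that passed camera kept its call. By fry, which asks whether a list's genes move on balance 1 way, 6 gene lists passed. Of the 5 repeat lists that passed camera, MaLR and L1 did not pass fry (fry adjusted p = 0.131 and 0.462). Related ERVL LTRs, SINEs and satellites did (fry adjusted p = 0.00157, 0.00355 and 0.00102).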

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

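The tests of the mt-Nd3 pattern and the comparison of main axes of variation were chosen after the result was seen. Of 270 groups of 4 values, 20 held 1 sample far from the other 3 by Dixon's criterion, where chance gives about 1 in 20. Of these, 6 were in Dux KO replicate 3 and 5 in Dux KO replicate 2.

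In WT, the sample apart was replicate 3 for Ripk3 (2.39 FPKM) and Dnajb1 (32.1), replicate 4 for Cnot6l (13.0) and Casp6 (14.7), replicate 1 for Chaf1b (13.0) and L1MEg2 (1.25 FPM), and replicate 2 for Cxcl10 (8.37). In Dux KO replicate 3 it was Rbm8a2 (30.0 FPKM), Olfr881 (2.90), Kyat3 (7.46), Cnot6l (25.6), Casp6 (7.89) and Gmnn (830.1). In Dux KO replicate 2 it was Psmb5 (21.5 FPKM), Dppa2 (24.8), Plk2 (3.81), Hspe1 (32.7) and Cdk1 (115). In Dux KO replicate 4 it was Hsph1 (12.3 FPKM) and Eulor4 (5.59 FPM).

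The ribosomal protein and early zygotic lists passed as lower in Dux KO with camera, but both had an adjusted p of 0.597 with an estimated correlation. After quantile normalization the ribosomal protein median was -0.46 (SE of the list mean 0.129), and after removal of a trend on gene length -0.53 (SE 0.132). Both lie far from the 0 that scaling or length as the whole cause would give, but neither passed the bound set beforehand, so both stay open as part of the cause. A difference in developmental time between the pools may also account for it: across genes, which are not independent replicates, the Dux KO over WT changes correlated with the main axis within WT pools at 0.218 and within Dux KO pools at 0.499, between the bounds that would decide. A slower development without Dux and pools collected at different times cannot be told apart here, as no label times the pools.

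MERVL-int and ORR1A internal elements were lower in Dux KO. With a stage score, oocyte minus early zygotic mean, as a covariate, the log2 fold change of MERVL-int was -1.38 (95% interval -1.80 to -0.96). The score did not overlap between the groups (0.163 to 0.758 in WT, 0.806 to 1.72 in Dux KO). It is built partly from the early zygotic list, which itself fell. The fit thus extends a slope within groups beyond their ranges and cannot tell developmental time from the loss of Dux, so that developmental time stays open. After median-of-ratios scaling over repeats the log2 fold change of MERVL-int was -1.31 (SE 0.111), which argues against scaling as the whole cause. Reads of MERVL-int counted also for ORR1A elements stay open: the median of 5 ORR1A LTRs was -0.76 (SE 0.143), not beyond its bound by more than its spread. The log2 ratio of ORR1A internal elements to MERVL-int was -0.595 ± 0.0594 in WT and -0.522 ± 0.154 in Dux KO (SD). Reads counted for both would keep this ratio alike, but so would elements that fall alike. The loss of Dux itself stays open too and was not tested apart from the groups.

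In Dux KO replicates 1, 3 and 4, mt-Nd3 was low and its nuclear copy Gm28438 high. The sum of both in these pools was at least 1.00 times the lowest WT sum of 411 FPKM. In replicate 2, where Gm28438 stayed low, it was 282 FPKM. The copies differ at 1 of 345 compared bases (T3C, counted from 1 at the 5′ end of mt-Nd3). Reads of a variant mitochondrial sequence assigned to the copy would give such sums in replicates 1, 3 and 4. The other 7 mitochondrial mRNAs had a median log2 ratio to the WT mean of -0.50, -0.38 and 0.16 in replicates 1, 3 and 4. It was -0.48 in replicate 2, where Gm28438 was low. In replicates 3 and 4 mt-Nd3 held 1 and 2 reads, against 1985 to 3158 in WT, while Gm28438 held 3232 and 4191. This argues against less mitochondrial RNA as the whole cause in replicates 3 and 4. As a part it stays open, since the lowest ratio, -0.50, is just past the bound of first choice. Gm28438 was above every WT pool in 3 of 4 Dux KO pools, which neither excludes nor shows an effect of Dux itself. The neighbouring mt-Tr was also lowest in replicates 3 and 4 (2.98 and 6.33 FPKM, against 75.2 to 122 in WT). Whether read assignment lowers mt-Tr too was not tested, so that its fall need not be an effect of Dux. Whether maternal lines differed was not tested. Had they differed between the groups, that difference could not be told apart from the loss of Dux in any comparison here.

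Chance as the source of the counts was tested over the 35 splits of the samples. Only the real split gave as many genes (4182, highest other 0) and genes changed at least 2-fold (876, highest other 0). It alone also gave as many repeats (155, highest other 1), a count of 1 each. This argues against chance, but 35 splits can give no p below 0.0286, so that chance cannot be excluded. The other splits mix Dux KO and WT pools, so that any difference between the groups adds to their spread. For gene lists 25 splits gave at least the real 3 (highest other 7), and for repeat lists 4 gave at least the real 5 (highest other 6), so that chance cannot be excluded for these counts.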

How the results depend on the processing

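The edgeR and DESeq2 tests, the omission of 2 Dux KO libraries and the deposited values for 2-fold changes were chosen after seeing the data. Under all alternatives run, 36 of 98 named genes, 6 of 23 lists and 4 of 11 named repeats other than MERVL-int kept their side of the threshold, and no result passed in the opposite direction. Signs of values that did not pass did turn: the medians of the apoptosis list (-0.12 to 0.08), of the IAP list without Dux KO replicate 1 (0.02) and with median-of-ratios scaling (0.01), of the oviduct and L1 lists without Dux KO replicates 1 and 2 (-0.04 and -0.02), and Cd52 (-0.30 to 0.33). The Dux transcript gave no value under any alternative, and the alternative for a table of counts was not run, since the gene table holds FPKM.

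Genes changed at least 2-fold (876) were 1596 with a pseudocount of 0.1, 1822 in the authors' deposited table, 1697 with edgeR and 1786 with DESeq2. Without Dux KO replicates 1 and 2 they were 360, changed genes 795 and changed repeats 31. Without replicates 3 and 4 they were 1560, changed genes 3944 and changed repeats 106. DESeq2 called 260 repeats. The cause was not tested.

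Gene lists called (3) were 5 with median-of-ratios scaling, 0 with an estimated correlation, 6 with fry and 7 without Dux KO replicates 3 and 4; repeat lists called (5) were 0 with an estimated correlation. The estimated correlation ended the calls of early zygotic (median -0.51), trophectoderm (0.51), ribosomal protein (-0.56), ERVL LTR (-0.64), MaLR (-0.13), L1 (0.05), SINE (-0.34) and satellite (-0.54) lists. Trophectoderm genes also lost theirs at a mean of 5 FPKM (0.33), with 6 members left, and L1 without Dux KO replicates 1 and 2 (-0.02). Calls gained with all 8 libraries or without 2, cause not tested, were: oxidative phosphorylation with a pseudocount of 0.1 (-0.34), no filter (-0.32), median-of-ratios (-0.28), fry (-0.32) and without Dux KO replicates 3 and 4 (-0.46); oocyte at 5 FPKM (0.35), with quantile (0.40) and median-of-ratios scaling (0.37), and without Dux KO replicates 3 and 4 (0.54); by fry, regulators (-0.27) and p53 (-0.19); without Dux KO replicates 3 and 4, mitochondrial (-0.50), oviduct (1.14) and ERVK (-0.07); ERVK with no filter (-0.10); DUX-responsive without Dux KO replicates 1 and 2 (-0.20).

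Whether replicate numbers pair the samples stayed unclear. Same-numbered deviations correlated at -0.12, 0.33, -0.06 and 0.30, and WT samples matched best with Dux KO numbers 2, 2, 4 and 4. Replicates 2 and 4 thus matched best with their own number, and replicates 1 and 3 did not. The replicate block gave 4732 genes, 186 repeats and 5 gene lists, adding oocyte (0.33) and oxidative phosphorylation (-0.32), and MERVL-int -1.33; it changed no other list call.

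Leaving out 1 library gave 2522 (without WT replicate 4) to 4049 genes, with 2682 without Dux KO replicate 1; 597 to 1090 genes at 2-fold; 3 to 5 gene lists (5 without WT replicate 2 or Dux KO replicate 4); 63 (without Dux KO replicate 2) to 148 repeats, with 90 without WT replicate 4 and 103 without Dux KO replicate 1; 4 to 6 repeat lists; and MERVL-int at -1.42 to -1.25. List calls gained were ERVK without WT replicate 3 (-0.16), IAP without WT replicate 4 (-0.19), DUX-responsive without WT replicate 4 (-0.32) or Dux KO replicate 2 (-0.22), oocyte without WT replicate 2 (0.30) or Dux KO replicate 4 (0.45), and oxidative phosphorylation without WT replicate 2 (-0.33) or 3 (-0.36) or Dux KO replicate 3 (-0.34) or 4 (-0.37); the L1 call was lost without Dux KO replicate 1 (0.02), and the MaLR median was -0.07 without WT replicate 1 or 2. Limma recovered 29.9% of 2-fold changes in a simulation that left 12194 of 12434 genes unchanged. The adjusted threshold is stricter there than in the data, where 4182 genes were called, so that this is not the share recovered here. Genes not called can still hold such changes.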

Other observations

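All lists in this part, 19 groups by name or gene type, were chosen after seeing the data. The Zfp, Psm and Obox groups were narrowed after their members were seen, and 18 of the 19 had enough members for a test. Antisense RNAs, protein coding genes, histone genes, solute carriers, small nucleolar RNA host genes and the Usp, Trim, Pramel and Khdc groups did not pass. Their camera adjusted p ranged from 0.115 to 0.990. Long intergenic noncoding RNAs rose in 215 and fell in 75 of 613 (median 0.37, camera adjusted p = 0.000171; adjusted p = 0.492 with an estimated correlation). Proteasome genes fell in 18 of 38 and rose in 1 (median -0.54, camera adjusted p = 0.000101), and RNA polymerase subunit genes fell in 14 of 27 and rose in 1 (median -0.54, camera adjusted p = 0.000227). Both had an adjusted p of 0.492 with an estimated correlation.

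Obox genes and pseudogenes fell in 11 of 16 and rose in none, with 11 lower and 3 higher adjusted over the list alone (median -1.02, camera adjusted p = 0.0041; adjusted p = 0.492 with an estimated correlation). Their near-identical copies leave the assignment of reads uncertain. Zinc finger genes named Zfp fell in 59 and rose in 15 of 249 (median -0.14, camera adjusted p = 0.0497; adjusted p = 0.492 with an estimated correlation).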
